A study of Hyphopichia burtonii with 8 samples.

How the data were processed

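The study measured RNA abundance by high-throughput sequencing in Hyphopichia burtonii, a yeast, strain KJJ43, a wild type isolated from Nuruk, a Korean fermentation starter. Precultured cells were inoculated at an OD600 of 0.6 into YPD, a rich medium of yeast extract, peptone and glucose, or into YPD supplemented with 1 M NaCl, 1 M KCl or 1 M sorbitol, and were cultured for 1 h. Cells equal to an OD of 5 were harvested, total RNA was extracted, and libraries were made with a strand-marking kit (NEBNext Ultra II Directional). The 4 media had 2 libraries each, 8 in all, and the design text names YPD as the control. How the duplicates were made (separate cultures or repeats of 1 culture) is not given in the sources used here.

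The deposited files held 1 value per gene and library for 6166 genes. The submitters' processing notes name TopHat and Cufflinks without versions. The genome build, the annotation, trimming and the strand setting of the counting are not given in the sources used here. The files state no unit. The values were taken as FPKM made by the authors (fragments per kilobase of gene, scaled to library depth), because they were not whole numbers, summed to between 1197308 and 1649003 per library, and, for genes with few fragments, fell near multiples of 1 step per library once multiplied by gene length. Any further scaling between libraries by the authors is not given in the sources used here, and none was added in the main analysis.

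Gene names came from the RefSeq annotation of assembly Hypbu1, which belongs to another strain, NRRL Y-1933. Of the 6166 genes, 6157 matched by locus tag, and 2346 of these had a symbol. A further 9 genes were listed in the files by symbol, 5 of which were also in the annotation, while 4, SNF3 among them, rest on the symbol alone. Symbols were given to genes by the annotation, mostly after genes of other yeasts, and functions named here are background knowledge on those relatives. Of 171 tRNA genes, 10 had a value above 0 and 3 were tested. No genome position is given, since the build behind the values is not known.

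The files gave no fragment counts. The size of the step between low values set the relative depth, which was highest in YPD replicate 2 and lowest in KCl replicate 2, with a ratio of 2.17 between them. Between 80.6% and 86.0% of the low values lay within 0.15 of a whole number of steps, against 36.7% to 46.9% of jittered values. One step equalled 0.0299 to 0.0649 FPKM for a gene with 1 kb left after a fitted length offset of 190 to 210 nt. The values of genes near 1 FPKM thus rested on limited numbers of fragments. These depths are estimates from the values, and no interval was drawn from them.

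Genes with at least 1 FPKM in at least 2 libraries were tested, which left 5765 genes, 2335 of them with a symbol. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 as 4 groups in 1 model over all 8 libraries, with an intensity trend in the prior variance. The model had 4 residual degrees of freedom (8.31 with the prior). The 6 comparisons between the 4 media were each adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. A gene called in a comparison is said to have risen or fallen, or to be higher or lower. Because 1 FPKM was added before the logarithm, log2 changes of genes near 1 FPKM are smaller than those of their raw means. The p-values measure only the spread between these libraries, 2 per medium. FPKM values are given as mean ± SD (n = 2 libraries) and log2 changes as the estimate ± its standard error from limma.

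Before the data were examined, 21 gene lists were fixed, and the 20 with at least 5 measured members were tested. They covered glycerol and polyol metabolism, cation transport, the HOG (high-osmolarity glycerol) pathway, trehalose and glycogen, heat shock and chaperones, oxidative stress defence, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrial ribosomal proteins, oxidative phosphorylation and the TCA cycle, glycolysis and fermentation, sterol synthesis, amino acid synthesis, the cell wall, the proteasome, DNA replication with histones and cell cycle, sugar transport, amino acid transport, translation factors with tRNA synthetases, and hyphal, adhesin and mating genes. The list for the mitochondrial genome and ribosomal RNA matched 2 measured genes, neither of that kind, and was not tested. Each list was tested against all other tested genes with limma's camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with limma's fry, adjusted over the 20 lists. The directional p of fry tests whether a list's genes move, on balance, 1 way, without comparing them with other genes. No list passed in any of the 6 comparisons with the estimated correlation, so every list call rests on the preset value.

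The genes named in the text followed a rule fixed at the same time. For each medium against YPD it took the 10 largest rises and the 10 largest falls among called genes with the same sign in all 4 pairs of libraries, at least 10 FPKM in the higher group and a symbol, and for each pair of added solutes the 5 largest in each direction. It also took every measured member of the glycerol, cation, HOG and trehalose lists, and the 4 members with the smallest adjusted p of any other list. The text names a part of these genes, picked after their values were seen, and some are not reported here. Replicate numbers were not used to pair libraries.

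The alternatives fixed in advance were a pseudocount of 0.1 or 5 FPKM, no filter or a filter of at least 10 FPKM in 2 libraries, scaling by median-of-ratios or by trimmed means of M-values, quantile normalization, limma without the trend, the replicate number as a block, a fit to only the 4 libraries compared, and leaving out each of the 8 libraries in turn. After removal of a library its group kept 1, which was assumed to vary like the others. Chosen after seeing the data were the counts of genes specific to a solute under all settings, the list members called without each library, the lists under quantile normalization, a correction for gene length, scaling of every library to the same total FPKM, 8 further gene lists, and the removals for genes that moved in opposite directions in 2 media or the same way in all 3. In simulations with 200 changed genes among 5716, 87.0% of changes of 1 log2 unit and 99.3% of those of 2 were called, with 4.72% false calls. Rates may be worse where genes vary together. Figures and depth estimates used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.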

Results

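The data are RNA abundances (FPKM per gene) from Hyphopichia burtonii KJJ43 cultured for 1 h in YPD, the control medium, or in YPD with 1 M NaCl, 1 M KCl or 1 M sorbitol, with 2 libraries per medium. The series asks how this yeast responds to high osmotic stress, and the 3 solutes had the same molarity. The salts dissociate and add chloride, so salt and sorbitol also differed in osmolarity. Libraries are written by medium and replicate number, as in NaCl 1. Where removal of 1 library ended the call of a named gene, the libraries and the largest adjusted p without one of them are given in brackets, in the paragraphs of that comparison. For a list, the number of members called is given beside each removed library, in brackets, that changed it by over 1.5 times. Between 5624 and 5699 genes reached 1 FPKM in a library. The 10 most abundant genes held 10.8% (NaCl 1) to 14.6% (YPD 1) of the summed FPKM.

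Replicates correlated across genes, which are not independent replicates, at r = 0.984 in YPD, 0.987 in NaCl, 0.982 in KCl and 0.985 in sorbitol (log2 values), and libraries of different media at 0.914 to 0.982. The first principal component held 53.8% of the variance and the second 18.1%.

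**Figure D1:**
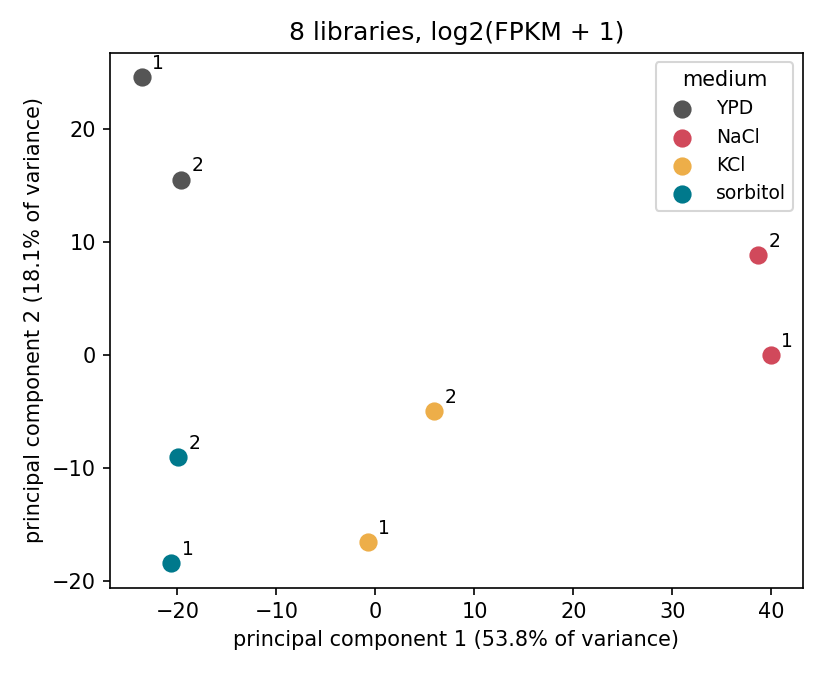
The 8 libraries by the first 2 principal components of log2(FPKM + 1) over 5765 genes, with the percent of variance on each axis and 1 point per library, coloured by medium. The first component (53.8%) sets the NaCl libraries apart from the others.

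In 1 M NaCl AHP1 (HYPBUDRAFT_140068), a thioredoxin peroxidase, rose from 3.46 ± 0.577 to 295 ± 8.63 FPKM (mean ± SD, n = 2 per medium; log2 change 6.06 ± 0.16, adjusted p = 7.2e-07), and PHR1 (HYPBUDRAFT_120065), a glucan-remodelling enzyme of the cell wall, from 1.15 ± 0.228 to 129 ± 32.6 (log2 change 5.90 ± 0.23, adjusted p = 1.9e-06). The secreted aspartyl protease gene SAP7 rose from 11.6 ± 0.790 to 333 ± 7.03 FPKM, ARG1 (argininosuccinate synthase) from 29.8 ± 8.76 to 625 ± 135, and ICL1 (isocitrate lyase, of the glyoxylate cycle) from 7.66 ± 0.251 to 152 ± 38.8. The urea transporter DUR3 (4.82 ± 0.55), the amine oxidase AMO1 (5.66 ± 0.66), the allantoin permease DAL4 (4.36 ± 0.74), SCW4 (4.05 ± 0.25) and the glutamate dehydrogenase GDH3 (4.04 ± 0.47) completed the 10 largest rises. CHA1 (HYPBUDRAFT_140979), a serine and threonine dehydratase, fell from 587 ± 207 to 37.4 ± 2.83 FPKM (log2 change -3.89 ± 0.23, adjusted p = 1.6e-05), and the copper transporter CTR1 from 989 ± 34.9 to 202 ± 50.4. HSP70 (-3.13 ± 0.67), HSP90 (-2.51 ± 0.23), CAP4 (-2.26 ± 0.24), ERG3 (-2.20 ± 0.17), HEM13 of haem synthesis (-2.04 ± 0.14), CTR2 (-2.01 ± 0.28), UPC2 (-2.01 ± 0.14) and ROA1 (-1.98 ± 0.24) made up the rest of the 10 largest falls. HSP70 (YPD 2 or NaCl 2, up to 0.064) lost the call.

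Of 67 genes of amino acid synthesis measured, 47 rose in NaCl, 5 fell and 15 were not called (50 higher and 7 lower adjusted over the list alone), with a median log2 change of 1.18 (camera adjusted p = 9.3e-15, and adjusted p = 0.29 with an estimated correlation). CPA1, which makes carbamoyl phosphate for arginine, rose from 10.4 ± 0.360 to 168 ± 30.2 FPKM (log2 change 3.88 ± 0.18, adjusted p = 5.2e-06), LYS22 (homocitrate synthase, lysine) by 3.87 ± 0.20, ILV2 (acetolactate synthase, branched-chain amino acids) by 2.90 ± 0.14 and ARG4 (argininosuccinate lyase) by 2.57 ± 0.13 log2 units. Among 16 amino acid transport genes 4 rose and 2 fell, with GNP1 at 1.23 ± 0.13 and GAP4 at -1.80 ± 0.18, and the list was not called (camera adjusted p = 0.33). The list of translation factors and tRNA synthetases (38 measured, 9 rose, 2 fell) was not called either (camera adjusted p = 0.44). The rises in amino acid transport became 1 (YPD 1 or NaCl 2). The rises in translation factors and tRNA synthetases became 2 (YPD 1), 4 (NaCl 1) and 5 (NaCl 2).

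Of 17 glycolysis and fermentation genes 14 fell in NaCl and 3 were not called (15 fell when adjusted over the list alone). The glycolysis median was -1.23 (camera adjusted p = 6.9e-10, and adjusted p = 0.29 with an estimated correlation). PGK1 (phosphoglycerate kinase) fell from 8912 ± 1157 to 3272 ± 209 FPKM (log2 change -1.44 ± 0.14, adjusted p = 1.8e-04), GPM1 (phosphoglycerate mutase) by 1.49 ± 0.14 and PFK2 (phosphofructokinase) by 1.72 ± 0.16 log2 units. In sterol synthesis 21 of 26 genes fell (23 adjusted over the list alone). The sterol list median was -0.79 (camera adjusted p = 1.7e-12, and adjusted p = 0.22 with an estimated correlation). ERG3, a sterol desaturase, dropped from 281 ± 63.9 to 59.5 ± 0.825 FPKM and ERG1, squalene epoxidase, from 786 ± 40.8 to 242 ± 6.97, with log2 changes of -2.20 ± 0.17 and -1.69 ± 0.12, and UPC2, a regulator of sterol genes, changed by -2.01 ± 0.14.

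Of 18 heat shock and chaperone genes 13 fell in NaCl (13 adjusted over the list alone). The chaperone list median was -0.97 (camera adjusted p = 1.9e-05, and adjusted p = 0.59 with an estimated correlation). HSP90 (HYPBUDRAFT_116403) dropped from 1483 ± 503 to 252 ± 21.5 FPKM (log2 change -2.51 ± 0.23, adjusted p = 1.6e-04), its co-chaperone genes AHA1 and HCH1 changed by -1.3 ± 0.20 and -1.2 ± 0.17, and HSP78, a mitochondrial chaperone, by -1.47 ± 0.22. The list's median per library, relative to the YPD mean, was -0.27 and 0.27 in the YPD libraries, so the controls themselves stood apart by 0.532 log2 units, against -1.0 and -0.94 in NaCl. Of 27 proteasome genes 13 fell and 14 were not called (15 fell when adjusted over the list alone), among them PRE9 (-0.74 ± 0.13) and RPT4 (-0.68 ± 0.11). The proteasome median was -0.38 (camera adjusted p = 8.4e-06, and adjusted p = 0.33 with an estimated correlation). The falls in heat shock became 8 (YPD 2 or NaCl 2). The falls in proteasome genes became 5 (YPD 1 or YPD 2), 2 (NaCl 1) and 6 (NaCl 2).

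The genes best known from osmotic responses moved in both directions. Of 9 glycerol and polyol genes 3 rose and 3 fell (same counts adjusted over the list alone), and the list was not called (camera adjusted p = 0.89). Its median (0.20) and mean (0.08) were positive while camera's direction was down. GPD1 and RHR2, which make glycerol from a glycolytic intermediate, fell from 1251 ± 69.7 to 777 ± 41.0 FPKM (log2 change -0.69 ± 0.14, adjusted p = 0.0078) and from 1507 ± 19.5 to 977 ± 45.4 (log2 change -0.63 ± 0.19, adjusted p = 0.040), and the xylitol dehydrogenase gene XYL2 changed by -0.84 ± 0.13. The aldose reductase gene GRE3 (0.90 ± 0.19), the arabitol dehydrogenase gene ARD (0.76 ± 0.19) and the dihydroxyacetone kinase gene DAK2 (0.86 ± 0.21) rose. GPD2 (0.41, adjusted p = 0.60), GUT1 and GUT2 were not called. GPD1 (NaCl 2, up to 0.052) and RHR2 (any YPD or NaCl library, up to 0.15) lost the call. GRE3 (YPD 1 or NaCl 2, up to 0.061) and ARD (YPD 1, NaCl 1 or NaCl 2, up to 0.12) lost the call. DAK2 (YPD 1, NaCl 1 or NaCl 2, up to 0.12) lost the call. The rises in glycerol and polyol genes became 0 (YPD 1 or NaCl 2) and 1 (NaCl 1).

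In cation transport 5 of 10 genes rose and 1 fell in NaCl (7 higher and 1 lower adjusted over the list alone). The cation transport median was 0.64 (camera adjusted p = 0.034, and adjusted p = 0.58 with an estimated correlation). HAK1, a high-affinity potassium transporter, rose from 15.6 ± 6.74 to 60.3 ± 3.11 FPKM (log2 change 1.95 ± 0.27, adjusted p = 0.0013), the vacuolar calcium pump gene PMC1 by 1.12 ± 0.23, the sodium/proton antiporter gene CNH1 by 0.72 ± 0.16, the plasma membrane proton pump gene PMA1 by 0.65 ± 0.13 and PMR1 by 0.52 ± 0.16, while the endosomal antiporter gene NHX1 fell (-0.54 ± 0.15). PHO89 (1.14, adjusted p = 0.054), VCX1 (0.64, adjusted p = 0.054), TRK1 and TOK1 were not called, though PHO89 was called without NaCl 2 (adjusted p = 0.034), KCl 1 (adjusted p = 0.042) or KCl 2 (adjusted p = 0.043) and VCX1 without either sorbitol library (adjusted p = 0.023). PMA1 (YPD 1 or NaCl 1, up to 0.070) and PMC1 (YPD 1 or NaCl 1, up to 0.077) lost the call. CNH1 (YPD 1 or NaCl 1, up to 0.080) and PMR1 (any YPD, NaCl or sorbitol library, up to 0.26) lost the call. NHX1 (YPD 1, NaCl 1 or NaCl 2, up to 0.17) lost the call. The rises in cation transport became 1 (YPD 1 or NaCl 1). Cation transport (adjusted p = 0.11 without YPD 2 and 0.086 without NaCl 1) lost the camera call.

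Of 19 HOG pathway genes 17 were not called. The phosphotransfer gene YPD1 rose (0.65 ± 0.14), the phosphatase gene PTC1 fell (-0.68 ± 0.17), and HOG1, the kinase that names the pathway, was at 128 ± 5.77 FPKM in YPD and 144 ± 9.90 in NaCl (log2 change 0.16 ± 0.13, adjusted p = 0.37). The list was not called (camera adjusted p = 0.99), with a median of -0.01 and a mean of 0.01. MSB2 (0.56, adjusted p = 0.10) was not called, but was without YPD 1. In the trehalose and glycogen list (12 measured) the trehalose synthesis genes TPS1 (-0.99 ± 0.13), TPS2 (-1.33 ± 0.13) and TPS3 (-0.63 ± 0.14) and the phosphoglucomutase gene PGM2 (-0.66 ± 0.13) fell, and GDB1, of glycogen breakdown, rose (1.12 ± 0.16; same counts adjusted over the list alone). That list was not called (camera adjusted p = 0.57), its median being 0.08 and its mean -0.05. YPD1 (YPD 1 or NaCl 2, up to 0.069) and PTC1 (YPD 1 or NaCl 1, up to 0.14) lost the call. TPS3 (YPD 1, YPD 2 or NaCl 2, up to 0.085) lost the call.

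Ribosome biogenesis genes had more rises than falls in NaCl: of 72, 30 rose, 4 fell and 38 were not called (31 higher and 4 lower adjusted over the list alone). The ribosome biogenesis median was 0.53 (camera adjusted p = 8.9e-05, and adjusted p = 0.73 with an estimated correlation). NOG2 (1.49 ± 0.26) and RRS1 (1.2 ± 0.19), of large-subunit assembly, rose and NOG1 (-1.09 ± 0.19) fell. The list's median stood at -0.25 and 0.25 in the YPD libraries relative to their mean, and at 0.63 and 0.43 in NaCl. Of 45 genes of DNA replication, histones and cell cycle 18 rose and 3 fell (19 higher and 3 lower adjusted over the list alone), among them the sliding clamp gene POL30 (1.35 ± 0.16), the ribonucleotide reductase gene RNR1 (1.80 ± 0.24) and RFA2 (1.2 ± 0.15). The DNA replication median was 0.33 (camera adjusted p = 0.011, and adjusted p = 0.59 with an estimated correlation). Of 26 cell wall genes 8 rose and 2 fell (9 higher and 2 lower adjusted over the list alone), with CRH11 at 1.96 ± 0.27 and PGA4 at 1.54 ± 0.16 beside PHR1 and SCW4. The cell wall median was 0.20 (camera adjusted p = 0.029, and adjusted p = 0.59 with an estimated correlation). The rises in ribosome biogenesis became 6 (YPD 1) and 2 (NaCl 1). The rises in the DNA replication list became 7 (YPD 1 or NaCl 1). Cell wall (adjusted p = 0.22 without YPD 2 and 0.086 without NaCl 1) lost the camera call.

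Cytosolic ribosomal protein genes had a median of -0.13 in NaCl, which turned to 0.13 under quantile normalization. With the values as given 2 of 66, RPS42 (-1.10 ± 0.13) and RPL9B (-1.02 ± 0.15), fell (2 adjusted over the list alone; camera adjusted p = 0.0075, and adjusted p = 0.84 with an estimated correlation), and under quantile normalization 13 rose and 2 fell (camera adjusted p = 6.5e-04). Of 51 genes of oxidative phosphorylation and the TCA cycle 3 rose and 10 fell (3 higher and 10 lower adjusted over the list alone), and quantile normalization ended that call (median -0.08, adjusted p = 0.58). The oxidative phosphorylation median was -0.16 (camera adjusted p = 0.0059, and adjusted p = 0.73 with an estimated correlation). The mitochondrial isocitrate dehydrogenase gene IDP1 (3.72 ± 0.14) rose against the list, and COX13 (-0.72 ± 0.13), a cytochrome oxidase subunit, fell. In oxidative stress defence 5 of 14 genes rose and 4 fell (camera adjusted p = 0.71), with SOD1 at 1.44 ± 0.13, the cytochrome c peroxidase gene CCP1 at -1.42 ± 0.13 and the flavohaemoglobin gene YHB1 at -1.78 ± 0.19 beside AHP1. The falls in ribosomal proteins became 4 (KCl 1 or KCl 2). The falls in the oxidative phosphorylation list became 6 (YPD 1), 3 (YPD 2 or NaCl 1) and 4 (NaCl 2). The rises in oxidative stress defence became 3 (YPD 1 or NaCl 2). Ribosomal proteins (adjusted p = 0.17 without YPD 2) lost the camera call.

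Of the remaining lists none was called. Mitochondrial ribosomal proteins had 2 of 18 higher (0 by limma without YPD 1 or NaCl 1; camera adjusted p = 0.72), and sugar transport had HXT2.1 (1.25 ± 0.20) higher and SNF3 (-0.86 ± 0.21) lower among 13 (camera adjusted p = 0.70). Of 21 hyphal, adhesin and mating genes 7 rose and 1 fell (camera adjusted p = 0.080), among them HGC1, a G1 cyclin-related gene (2.09 ± 0.22), NRG1 (1.32 ± 0.26) and SPS20 (0.96 ± 0.13). The mitochondrial genome and ribosomal RNA list matched only RRN11 and RRN3, which in other yeasts encode RNA polymerase I factors, so it held no gene of its kind and was not tested. SNF3 (YPD 1 or NaCl 1, up to 0.14) lost the call. The rises in the hyphal list became 4 (NaCl 1).

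In all, 1585 of 5765 genes were called between NaCl and YPD, 920 higher and 665 lower (2306 at an unadjusted p under 0.05), and 715 differed by at least 1 log2 unit. Under quantile normalization the split turned to 794 higher and 998 lower. Camera called 11 of 20 lists and fry 10, and with an estimated correlation camera called 0 (3 at an unadjusted p under 0.05). The count fell to 767 without YPD 1, 701 without NaCl 1 and 968 without NaCl 2.

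**Figure D2:**
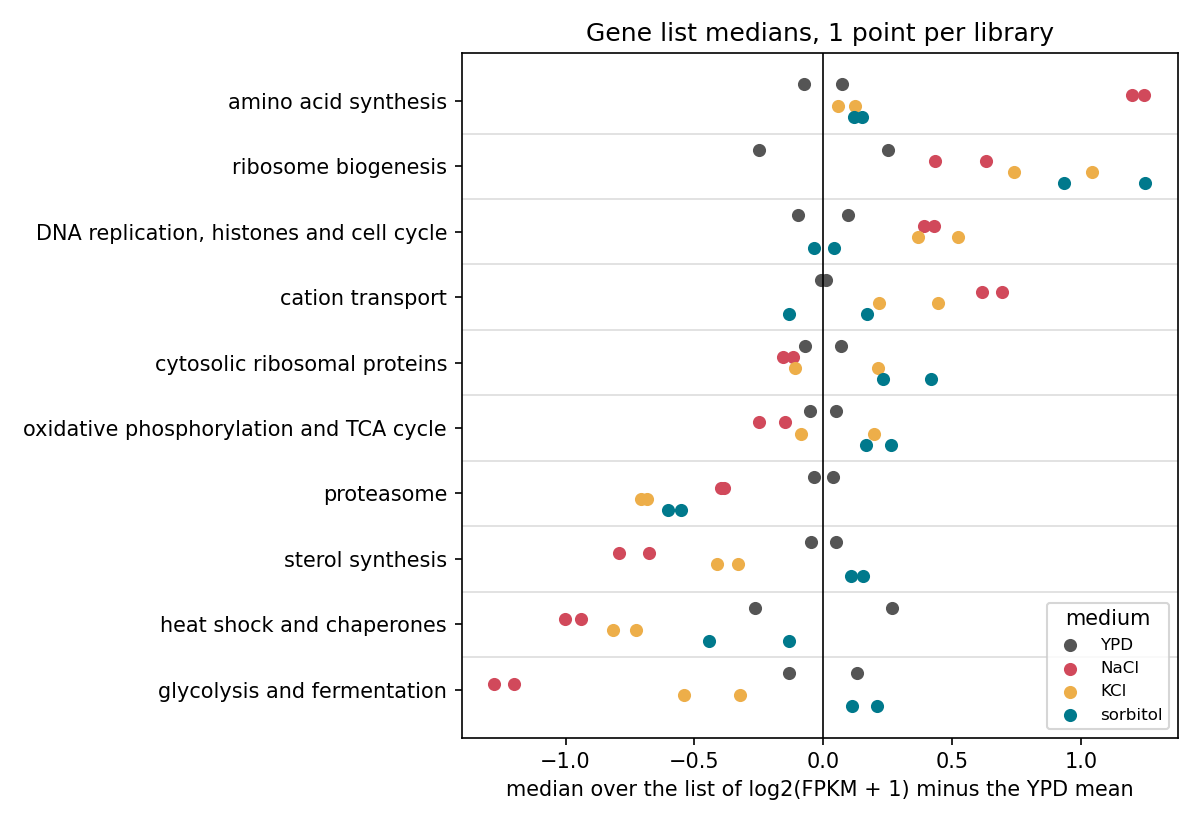
Median over each of 10 gene lists of log2(FPKM + 1) minus the YPD mean of each gene (horizontal axis), with 1 point per library, coloured by medium. Ribosome biogenesis stands at 1.25 and 0.93 in sorbitol and at -0.25 and 0.25 in YPD. The median change of cytosolic ribosomal proteins in NaCl (-0.13) becomes 0.13 under quantile normalization.

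**Figure D3:**
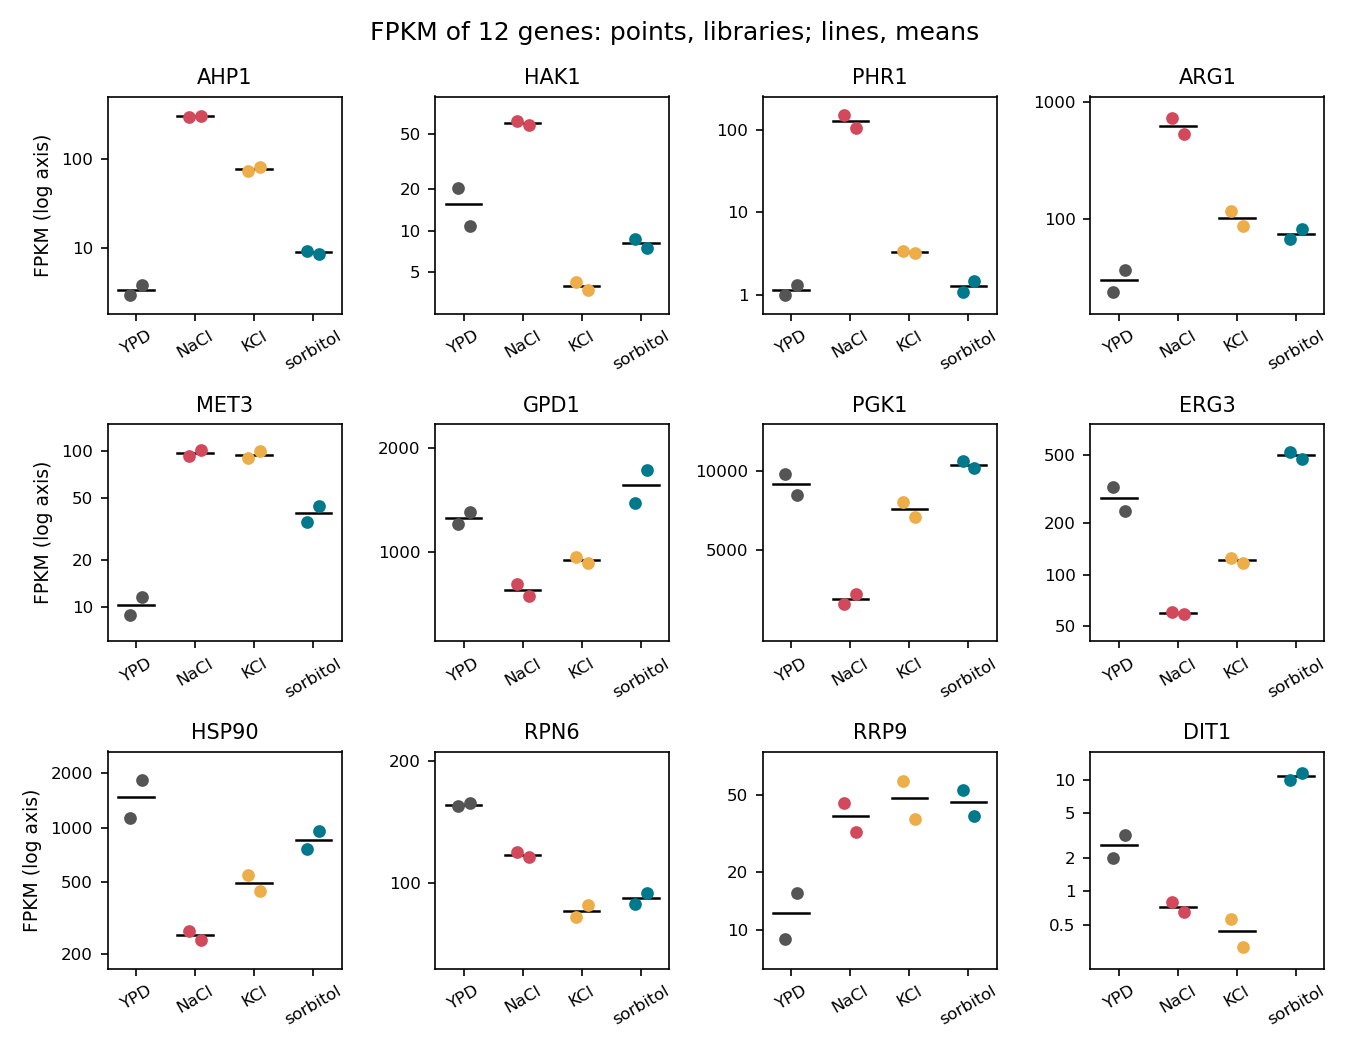
FPKM (log scale) of 12 named genes in each of the 8 libraries, with 1 point per library coloured by medium and the mean of each medium as a line. AHP1 rises from 3.46 FPKM in YPD to 295 in NaCl, and HSP90 falls from 1483 to 252.

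In 1 M KCl the peroxidase gene AHP1 and the sulfate assimilation genes MET3 and MET14 rose, and the potassium transporter gene HAK1 fell. AHP1 rose from 3.46 ± 0.577 to 76.5 ± 6.37 FPKM (n = 2 per medium; log2 change 4.12 ± 0.16, adjusted p = 1.9e-05), the ATP sulfurylase gene MET3 (HYPBUDRAFT_122453) from 10.3 ± 1.97 to 95.2 ± 7.21 (log2 change 3.10 ± 0.19, adjusted p = 7.6e-05) and the adenylylsulfate kinase gene MET14 from 38.7 ± 6.43 to 224 ± 41.8. DDR48 (3.02 ± 0.23), SAP7 (2.67 ± 0.14), ICL1 (2.45 ± 0.31) and DAL4 (3.61 ± 0.74) were also among the 10 largest rises. HAK1, which rose in NaCl, fell from 15.6 ± 6.74 to 4.01 ± 0.355 FPKM (log2 change -1.67 ± 0.27, adjusted p = 0.0097), and HSP90 fell from 1483 ± 503 to 496 ± 75.1. Other large falls were in HSP70 (-3.07 ± 0.67), CHA1 (-1.93 ± 0.23), the zinc transporter ZRT2 (-1.65 ± 0.25), HSP78 (-1.55 ± 0.22) and GPX3 (-1.38 ± 0.19). DAL4 (YPD 1 or KCl 2, up to 0.14) and HSP70 (any YPD or KCl library, up to 0.11) lost the call.

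Of 72 ribosome biogenesis genes 33 rose in KCl (54 adjusted over the list alone) and the rest were not called. The ribosome biogenesis median was 0.88 (camera adjusted p = 4.2e-18, and adjusted p = 0.52 with an estimated correlation). The list's median relative to the YPD mean was 1.04 and 0.74 in the KCl libraries against -0.25 and 0.25 in YPD. NOG2 rose by 1.73 ± 0.26, RRP9 by 1.88 ± 0.32 and RRS1 by 1.11 ± 0.19 log2 units. Of 27 proteasome genes 23 fell (24 adjusted over the list alone), such as RPN6 (-0.87 ± 0.12), PRE3 (-0.82 ± 0.12) and RPN10 (-0.97 ± 0.14). The proteasome median was -0.68 (camera adjusted p = 2.9e-17, and adjusted p = 0.18 with an estimated correlation). Of 18 chaperone genes 8 fell (11 adjusted over the list alone), with AHA1 at -1.26 ± 0.20 and HCH1 at -1.09 ± 0.17. The chaperone list median was -0.80 (camera adjusted p = 6.7e-06, and adjusted p = 0.52 with an estimated correlation). That list's median was -0.73 and -0.82 in the KCl libraries, against -0.27 and 0.27 in YPD. The rises in ribosome biogenesis became 1 (YPD 1), 2 (KCl 1) and 18 (KCl 2). The falls in proteasome genes became 5 (YPD 1), 10 (YPD 2), 6 (KCl 1) and 14 (KCl 2). The falls in chaperones became 4 (YPD 2, KCl 1 or KCl 2). NOG2 (YPD 1, up to 0.052) and RRP9 (YPD 1 or KCl 1, up to 0.076) lost the call. RRS1 (YPD 1 or KCl 1, up to 0.074) lost the call.

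Sterol genes (26) had 8 lower in KCl (13 adjusted over the list alone), with ERG6 at -1.21 ± 0.15, ERG2 at -1.29 ± 0.18 and ERG3 at -1.19 ± 0.17. The sterol list median was -0.37 (camera adjusted p = 1.1e-09, and adjusted p = 0.18 with an estimated correlation). Of 17 glycolytic genes 3 fell, GPM2 (-0.97 ± 0.17), PFK1 (-0.62 ± 0.12) and FBA1 (-0.50 ± 0.13), or 8 adjusted over the list alone. The glycolysis median was -0.41 (camera adjusted p = 5.2e-06, and adjusted p = 0.38 with an estimated correlation). DNA replication genes (45) had 10 higher (13 adjusted over the list alone), POL30 among them (1.02 ± 0.16). The DNA replication median was 0.45 (camera adjusted p = 5.2e-06, and adjusted p = 0.38 with an estimated correlation). Of 67 amino acid synthesis genes 11 rose and 2 fell (14 higher and 2 lower adjusted over the list alone), with MET10 at 1.2 ± 0.13 and ARG1 at 1.74 ± 0.25. The amino acid median was 0.10 (camera adjusted p = 0.026, and adjusted p = 0.67 with an estimated correlation). The falls in sterol synthesis became 3 (YPD 1). The falls in glycolysis became 0 (YPD 1 or KCl 2) and 1 (KCl 1). The rises in the DNA replication list became 1 (YPD 1), 4 (YPD 2 or KCl 2) and 6 (KCl 1). The rises in amino acid synthesis became 4 (YPD 1), 7 (YPD 2) and 6 (KCl 1). Amino acid synthesis (adjusted p = 0.18 without YPD 1 and 0.056 without KCl 1) lost the camera call. GPM2 (any YPD or KCl library, up to 0.057) and PFK1 (YPD 1, KCl 1 or KCl 2, up to 0.13) lost the call. FBA1 (any library, up to 0.27) and POL30 (YPD 1, up to 0.067) lost the call.

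Among glycerol and polyol genes ARD rose in KCl (0.86 ± 0.19) and the other 8 were not called, including GPD1 (-0.40, adjusted p = 0.10) and RHR2 (-0.60, adjusted p = 0.083), of which RHR2 was called without sorbitol 1 (adjusted p = 0.030) or sorbitol 2 (adjusted p = 0.030). GPD2 was called without KCl 2 (adjusted p = 0.037). Adjusted over the list alone, 1 rose and 3 fell (camera adjusted p = 0.41). In cation transport the sodium-phosphate cotransporter gene PHO89 (from 0.364 ± 0.0177 to 7.26 ± 3.01 FPKM, 2.55 ± 0.38) and CNH1 (1.16 ± 0.16) rose and HAK1 fell (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.31). Trehalose and glycogen genes (12) had TPS1 (-0.72 ± 0.13), TPS2 (-0.53 ± 0.13) and TPS3 (-0.64 ± 0.14) lower and UGP1 (0.58 ± 0.13) higher (median -0.41; camera adjusted p = 0.0080, and adjusted p = 0.23 with an estimated correlation; 1 higher and 4 lower adjusted over the list alone). By limma 0 of 19 HOG pathway genes were called (2 at an unadjusted p under 0.05, 0 by limma without the trend; camera adjusted p = 0.83), with HOG1 at 0.00, adjusted p = 1.000. ARD (YPD 1 or KCl 1, up to 0.16) and PHO89 (YPD 1, up to 0.052) lost the call. TPS1 (YPD 1, YPD 2 or KCl 2, up to 0.066) and TPS2 (any library, up to 0.17) lost the call. TPS3 (any YPD or KCl library, up to 0.13) and UGP1 (YPD 1, YPD 2, NaCl 1, NaCl 2 or KCl 1, up to 0.16) lost the call. Trehalose and glycogen (adjusted p = 0.056 without KCl 1) lost the camera call.

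KCl and YPD differed in 632 of 5765 genes, 372 higher and 260 lower in KCl (1535 at an unadjusted p under 0.05), and 304 by at least 1 log2 unit. Camera called 8 of 20 lists, fry 7, and camera with an estimated correlation 0 (3 at an unadjusted p under 0.05). Under quantile normalization camera also called the cell wall (median 0.08, adjusted p = 0.036), cytosolic ribosomal protein (0.04, adjusted p = 0.018) and oxidative phosphorylation lists (0.03, adjusted p = 0.045). The count fell to 114 without YPD 1, 357 without YPD 2, 204 without KCl 1 and 295 without KCl 2.

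In 1 M sorbitol PGA18 (HYPBUDRAFT_148609) rose from 17.9 ± 6.14 to 111 ± 0.788 FPKM (n = 2 per medium; log2 change 2.60 ± 0.21, adjusted p = 0.0027), BUD22 of ribosome assembly from 3.44 ± 0.944 to 28.8 ± 20.3 (log2 change 2.57 ± 0.52, adjusted p = 0.036) and MET3 by 1.86 ± 0.19 log2 units (adjusted p = 0.0057). MAK16 (2.19 ± 0.49), RRP9 (1.84 ± 0.32) and MET14 (1.83 ± 0.19) were among the other large rises. CSR1 (-1.39 ± 0.24), the haem oxygenase gene HMX1 (-1.31 ± 0.24) and the proteasome genes RPN6 (-0.76 ± 0.12) and PRE3 (-0.72 ± 0.12) were among the largest falls. Of the 38 named genes called in sorbitol only PGA18 was called after removal of each of the 8 libraries in turn. BUD22 (YPD 1, YPD 2, NaCl 1, NaCl 2 or sorbitol 1, up to 0.15) and MAK16 (YPD 1, YPD 2, NaCl 1, NaCl 2 or sorbitol 1, up to 0.22) lost the call. RRP9 (YPD 1, NaCl 1, NaCl 2 or sorbitol 1, up to 0.15) and MET3 (YPD 1, up to 0.052) lost the call. MET14 (YPD 1 or sorbitol 1, up to 0.061) and CSR1 (any YPD, NaCl or sorbitol library, up to 0.13) lost the call. HMX1 (YPD 1, NaCl 1, NaCl 2, sorbitol 1 or sorbitol 2, up to 0.13) and RPN6 (any YPD, NaCl or sorbitol library, up to 0.13) lost the call. PRE3 (any YPD, NaCl or sorbitol library, up to 0.13) lost the call.

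Of 72 ribosome biogenesis genes 41 rose in sorbitol (71 adjusted over the list alone), with library medians of 1.25 and 0.93 against -0.25 and 0.25 in YPD. The ribosome biogenesis median was 1.11 (camera adjusted p = 4.1e-33, and adjusted p = 0.55 with an estimated correlation). Proteasome genes (27) had 13 lower (25 adjusted over the list alone). The proteasome median was -0.58 (camera adjusted p = 9.7e-15, and adjusted p = 0.27 with an estimated correlation). Camera also called cytosolic ribosomal proteins as higher (median 0.32, 0.03 under quantile normalization; camera adjusted p = 7.7e-14, and adjusted p = 0.55 with an estimated correlation), although limma called only RPS42 of 66 (1.06 ± 0.13; 1 adjusted over the list alone; 30 at an unadjusted p under 0.05). Of 38 translation factors and tRNA synthetases TIF4631 rose (0.67 ± 0.12; 1 adjusted over the list alone). The translation factor median was 0.30 (camera adjusted p = 2.3e-07, and adjusted p = 0.55 with an estimated correlation). Mitochondrial ribosomal proteins and oxidative phosphorylation genes were called as lists with 0 members called by limma in each, 8 at an unadjusted p under 0.05 in each and 0 by limma without the trend. Their medians were 0.47 and 0.21 (camera adjusted p = 2.5e-05 and 1.1e-05). With an estimated correlation adjusted p was 0.55 for each. Quantile normalization ended the oxidative phosphorylation call (median 0.01, adjusted p = 0.64). The rises in ribosome biogenesis became 0 (YPD 1 or sorbitol 1), 5 (NaCl 1 or NaCl 2) and 26 (sorbitol 2). The falls in proteasome genes became 0 (any YPD, NaCl or sorbitol library). RPS42 (YPD 1 or sorbitol 1, up to 0.11) and TIF4631 (any YPD, NaCl or sorbitol library, up to 0.16) lost the call.

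Among 67 amino acid synthesis genes 6 rose in sorbitol (7 higher and 1 lower adjusted over the list alone), including MET10 (0.83 ± 0.13) and ARG1 (1.31 ± 0.25), a list call that quantile normalization ended (median 0.03, adjusted p = 0.15). The amino acid median was 0.14 (camera adjusted p = 0.019, and adjusted p = 0.55 with an estimated correlation). Cell wall genes (26) had PGA4 (0.84 ± 0.16) and PIR1 (0.75 ± 0.16) higher (10 higher and 2 lower adjusted over the list alone). The cell wall median was 0.31 (camera adjusted p = 0.0023, and adjusted p = 0.55 with an estimated correlation). Of the trehalose and glycogen list limma called 0 of 12 (5 lower at an unadjusted p under 0.05, 3 lower adjusted over the list alone, 0 without the trend). The trehalose and glycogen median was -0.52 (camera adjusted p = 0.038, and adjusted p = 0.55 with an estimated correlation). The sterol genes ERG3 (0.85 ± 0.17) and ERG1 (0.67 ± 0.12) rose, and their list was not called (camera adjusted p = 0.074). Heat shock was not called as a list either, but was under quantile normalization (median -0.43, adjusted p = 0.011). The chaperone list median was -0.32 (camera adjusted p = 0.074). The rises in amino acid synthesis became 0 (YPD 1), 3 (YPD 2), 2 (NaCl 1, NaCl 2 or sorbitol 2) and 1 (sorbitol 1). Amino acid synthesis (adjusted p = 0.18 without YPD 1 and 0.18 without sorbitol 2) lost the camera call. Cell wall (adjusted p = 0.11 without YPD 2) lost the camera call. Trehalose and glycogen (adjusted p = 0.061 without YPD 2 and 0.13 without sorbitol 1) lost the camera call. MET10 (any YPD, NaCl or sorbitol library, up to 0.13) and ARG1 (YPD 1, NaCl 1, NaCl 2, sorbitol 1 or sorbitol 2, up to 0.17) lost the call. PGA4 (any YPD, NaCl or sorbitol library, up to 0.14) and PIR1 (any YPD, NaCl or sorbitol library, up to 0.18) lost the call. ERG3 (any YPD, NaCl or sorbitol library, up to 0.15) and ERG1 (any YPD, NaCl or sorbitol library, up to 0.13) lost the call.

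Limma called 0 of 9 glycerol and polyol genes in sorbitol (3 at an unadjusted p under 0.05, 2 higher when adjusted over the list alone, 0 by limma without the trend; camera adjusted p = 0.55). RHR2 (0.70, adjusted p = 0.072) and GPD1 (0.31, adjusted p = 0.21) were among them. In the cation list PMA1 rose (0.69 ± 0.13, 1 adjusted over the list alone, camera adjusted p = 0.72). HAK1 (-0.80, adjusted p = 0.12) was called, among the removals of 1 library, only without YPD 2. HOG pathway genes gave 0 calls of 19 by limma (1 at an unadjusted p under 0.05, 0 without the trend; camera adjusted p = 0.60), and glycolytic genes 0 of 17 (0 at an unadjusted p under 0.05, 0 without the trend; camera adjusted p = 0.19). PMA1 (any YPD, NaCl or sorbitol library, up to 0.16) lost the call.

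Sorbitol and YPD differed in 286 of 5765 genes, 216 higher and 70 lower in sorbitol (1439 at an unadjusted p under 0.05), and 161 by at least 1 log2 unit. Quantile normalization gave 163 higher and 93 lower. Camera called 9 of 20 lists, fry 2, and camera with an estimated correlation 0 (1 at an unadjusted p under 0.05). The count fell most without YPD 1 or sorbitol 1. It also fell without either NaCl library, though these do not enter the log2 changes, only the error estimate. The falls thus mix lost power with dependence on a library. The genes called without YPD 1 were PGA18, HYPBUDRAFT_216990, HYPBUDRAFT_164360 and, as lower, HYPBUDRAFT_95311, and without sorbitol 1 PGA18, MET3, HYPBUDRAFT_157712, HYPBUDRAFT_216990 and HYPBUDRAFT_164360; those without a symbol were chosen for naming after their values were seen.

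In all 3 media 114 genes were higher and 22 lower than in YPD, 61 and 12 with a symbol. Of the 61, 23 were ribosome biogenesis genes (of 72 among 2335, Fisher's exact test, adjusted p = 1.3e-19), such as NOG2 and RRS1. Of the 12, 9 were proteasome genes (of 27, adjusted p = 3.6e-15), such as PRE3. These p-values overstate the evidence if list members move together. All 23 were lost without YPD 1 or sorbitol 1, and all 9 without any 1 YPD, NaCl or sorbitol library. Higher in all 3 were also AHP1 (log2 changes of 6.06, 4.12 and 1.18 in NaCl, KCl and sorbitol), MET3 (3.13, 3.10 and 1.86), MET14 (2.35, 2.50 and 1.83), ARG1 (4.36, 1.74 and 1.31), SAP7, DDR48 and GNP1. In sorbitol NOG2, RRS1, AHP1, SAP7, DDR48 and GNP1 (YPD 1 or sorbitol 1, up to 0.13) lost the call, and in NaCl PRE3 (any YPD or NaCl library, up to 0.11). Independent calls would share 2.22 higher and 0.364 lower genes, a count that ignores the shared YPD libraries. In 50 simulations of unchanged media with shared simulated controls 0.02 and 0 were shared on average, a count that ignores the changes. The part of the overlap due to the controls was not estimated. The 136 genes became 4 without YPD 1, 31 without NaCl 1, 35 without NaCl 2, 46 without KCl 1, 83 without KCl 2 and 4 without sorbitol 1.

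Log2 changes against YPD correlated across genes, which are not independent replicates, at r = 0.694 between NaCl and KCl (Spearman's rho 0.681), 0.599 between KCl and sorbitol (0.541) and 0.307 between NaCl and sorbitol (0.248). Unchanged media, simulated against the same YPD libraries, gave r = 0.496, 0.492 and 0.496. Covariances of 0.316, 0.159 and 0.123 exceeded the simulated ones by 0.286, 0.130 and 0.0931. NaCl and KCl shared 290 higher and 184 lower genes (59.4 and 29.99 if independent), KCl and sorbitol 148 and 34 (13.9 and 3.16), and NaCl and sorbitol 132 and 27 (34.5 and 8.07). Unchanged media shared 0 to 0.04, a count that ignores the changes.

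**Figure D4:**
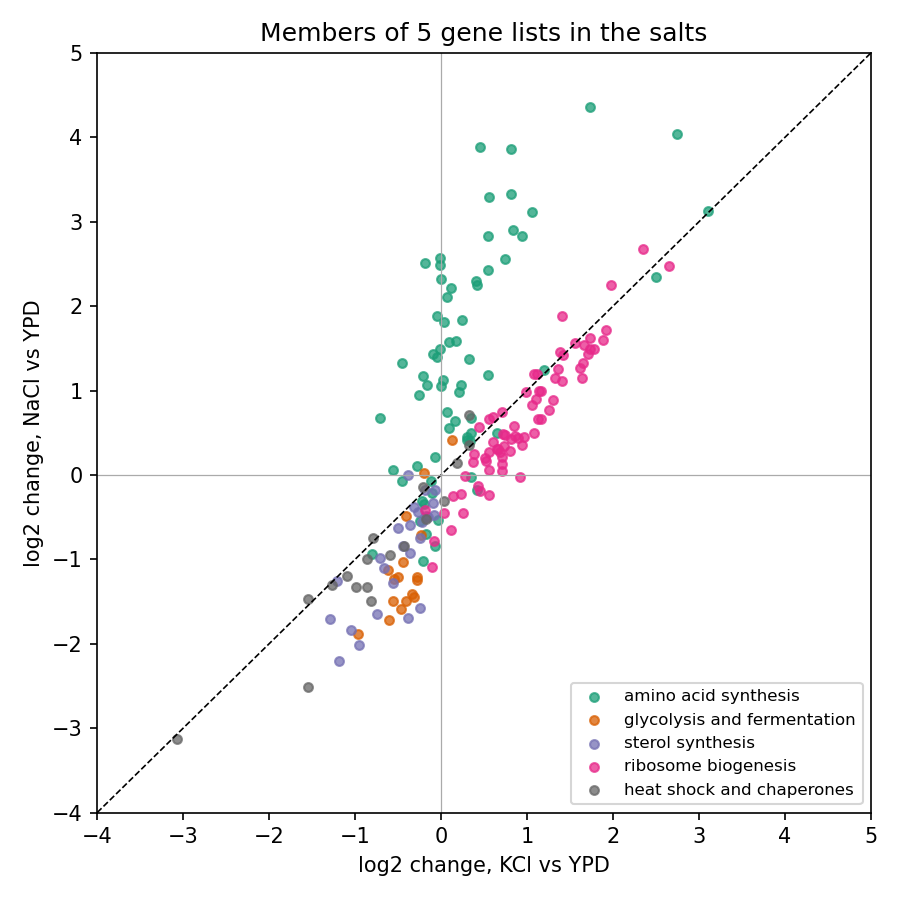
Log2 change against YPD in KCl (horizontal axis) and in NaCl (vertical axis) of the members of 5 gene lists, with 1 point per gene, coloured by list, and a dashed line of equal change. Amino acid synthesis has a median of 1.18 in NaCl and 0.10 in KCl, and ribosome biogenesis of 0.53 and 0.88.

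The 2 salts, at the same molarity, set sodium against potassium. PHR1 was higher in NaCl (129 ± 32.6 FPKM) than in KCl (3.28 ± 0.136; n = 2 per medium; log2 change 4.90 ± 0.23, adjusted p = 2.2e-05), as were HAK1 (60.3 ± 3.11 against 4.01 ± 0.355; log2 change 3.62 ± 0.27, adjusted p = 1.1e-04), HYU1 (3.58 ± 0.39), CPA1 (3.43 ± 0.18) and the alcohol acetyltransferase gene ATF1 (3.28 ± 0.26). Lower in NaCl were RPS42 (-2.02 ± 0.13), CHA1 (-1.96 ± 0.23), ROA1 (-1.96 ± 0.24), the iron permease gene FTR2 (-1.77 ± 0.19) and TIF5 (-1.75 ± 0.14). In amino acid synthesis 38 of 67 genes were higher in NaCl and 4 lower (44 higher and 5 lower adjusted over the list alone), with ARG4 at 2.58 ± 0.13, ARG3 at 2.50 ± 0.15 and ARO8 at 2.10 ± 0.13. The amino acid median was 1.10 (camera adjusted p = 8.1e-19, and adjusted p = 0.29 with an estimated correlation). Of 17 glycolytic genes 13 were lower in NaCl (13 adjusted over the list alone), with PGK1 at -1.13 ± 0.14 and TDH3 at -0.93 ± 0.12. The glycolysis median was -0.92 (camera adjusted p = 1.2e-08, and adjusted p = 0.35 with an estimated correlation). Sterol genes (26) had 8 lower (12 adjusted over the list alone), with ERG1 at -1.31 ± 0.12. The sterol list median was -0.37 (camera adjusted p = 2.8e-07, and adjusted p = 0.29 with an estimated correlation). The falls in glycolysis became 5 (NaCl 1 or NaCl 2) and 7 (KCl 1). The falls in sterol synthesis became 4 (NaCl 1, NaCl 2 or KCl 1) and 5 (KCl 2).

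Between NaCl and KCl 8 of 51 oxidative phosphorylation genes were lower and 2 higher in NaCl (9 and 2 adjusted over the list alone), and 6 of 72 ribosome biogenesis genes were lower (2 adjusted over the list alone). The medians of these 2 lists were -0.24 and -0.29 (camera adjusted p = 2.7e-05 and 3.2e-05). With an estimated correlation adjusted p was 0.85 for each. Of 27 proteasome genes 2 were higher and 25 not called (10 higher when adjusted over the list alone). The proteasome median was 0.32 (camera adjusted p = 2.7e-05, and adjusted p = 0.39 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.19, or 0.07 under quantile normalization, which ended the call (adjusted p = 0.053; camera adjusted p = 2.1e-05, and adjusted p = 0.85 with an estimated correlation). GRE3 (0.77 ± 0.19) was the only glycerol or polyol gene that differed (camera adjusted p = 0.76), and PHO89 was lower in NaCl (-1.40 ± 0.38), as was TPS2 (-0.80 ± 0.13), while GDB1 (1.42 ± 0.16) was higher. GPD2 (1.53, adjusted p = 0.12) was not called, but was without KCl 2. HOG pathway genes gave 0 of 19 calls by limma (0 at an unadjusted p under 0.05, 0 without the trend). The falls in oxidative phosphorylation became 4 (YPD 1 or YPD 2), 0 (NaCl 1) and 1 (NaCl 2 or KCl 1). The falls in ribosome biogenesis became 3 (YPD 1 or YPD 2) and 0 (NaCl 1, NaCl 2 or KCl 1). The rises in proteasome genes became 1 (YPD 1, YPD 2, NaCl 2, sorbitol 1 or sorbitol 2) and 0 (NaCl 1, KCl 1 or KCl 2). Cytosolic ribosomal proteins (adjusted p = 0.25 without KCl 1) lost the camera call. GRE3 (YPD 1, YPD 2, NaCl 1, NaCl 2 or KCl 1, up to 0.22) and PHO89 (YPD 1, YPD 2, NaCl 1, NaCl 2, KCl 1, sorbitol 1 or sorbitol 2, up to 0.26) lost the call. TPS2 (NaCl 2 or KCl 1, up to 0.058) lost the call.

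In all, 622 of 5765 genes differed between NaCl and KCl, 392 higher and 230 lower in NaCl (1442 at an unadjusted p under 0.05), 298 of them by at least 1 log2 unit. Camera called 7 lists, fry 5, and camera with an estimated correlation 0 (2 at an unadjusted p under 0.05). The count fell to 223 without NaCl 1, 297 without NaCl 2 and 261 without KCl 1.

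NaCl was also compared with sorbitol, a non-ionic solute. PHR1 (log2 change 5.82 ± 0.23, adjusted p = 2.4e-06), AHP1 (295 ± 8.63 FPKM in NaCl against 9.08 ± 0.529 in sorbitol, n = 2 each), SCW4 (4.22 ± 0.25), AMO1 (4.20 ± 0.66) and HYU1 (4.14 ± 0.39) were higher in NaCl. CHA1 (-3.08 ± 0.23), ERG3 (59.5 ± 0.825 against 502 ± 34.7 FPKM; log2 change -3.05 ± 0.17, adjusted p = 9.5e-06), the inositol transporter gene ITR1 (-2.78 ± 0.20), DIT1 (-2.76 ± 0.25) and CTR1 (-2.68 ± 0.17) were lower. The glycerol synthesis genes GPD1 (log2 change -0.99 ± 0.14, adjusted p = 0.0011) and RHR2 (log2 change -1.32 ± 0.19, adjusted p = 0.0013) and XYL2 (-1.35 ± 0.13) were lower in NaCl, and GRE3 (1.2 ± 0.19) and ARD (0.89 ± 0.19) higher, so the list of 9 was split (3 higher and 3 lower adjusted over the list alone; median 0.22, mean 0.00, camera's direction down; camera adjusted p = 0.90). HAK1 (2.75 ± 0.27), PHO89 (1.2 ± 0.38), PMC1 (0.98 ± 0.23) and VCX1 (0.71 ± 0.21) were higher in NaCl (5 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.11). Of 12 trehalose and glycogen genes 5 were higher, such as GDB1 (1.79 ± 0.16), and 3 lower, such as TPS1 (-1.01 ± 0.13) and TPS2 (-1.63 ± 0.13) (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.73). In the HOG pathway 2 of 19 genes, PTC1 and RCK2, were lower (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.87). PHO89 (YPD 1, YPD 2, NaCl 1, sorbitol 1 or sorbitol 2, up to 0.26) and PMC1 (NaCl 1 or sorbitol 2, up to 0.10) lost the call. VCX1 (NaCl 1, NaCl 2 or sorbitol 2, up to 0.17) and PTC1 (NaCl 1, NaCl 2 or sorbitol 1, up to 0.17) lost the call. RCK2 (NaCl 1, NaCl 2 or sorbitol 2, up to 0.067) lost the call. The rises in the trehalose list became 3 (NaCl 1 or sorbitol 1) and 1 (NaCl 2).

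Sterol genes had 22 of 26 lower in NaCl than in sorbitol (22 adjusted over the list alone), with UPC2 at -2.56 ± 0.14 and ERG1 at -2.37 ± 0.12. The sterol list median was -0.81 (camera adjusted p = 8.4e-13, and adjusted p = 0.21 with an estimated correlation). Amino acid synthesis had 44 of 67 higher and 5 lower (46 higher and 6 lower adjusted over the list alone), with LYS22 at 3.67 ± 0.20 and LEU1 at 2.95 ± 0.16. The amino acid median was 0.97 (camera adjusted p = 4.8e-12, and adjusted p = 0.32 with an estimated correlation). Glycolysis had 14 of 17 lower and 1 higher (1 higher and 14 lower adjusted over the list alone), with PFK2 at -2.0 ± 0.16. The glycolysis median was -1.36 (camera adjusted p = 1.8e-09, and adjusted p = 0.32 with an estimated correlation). Of 18 heat shock genes 9 were lower, such as HSP104 (-1.68 ± 0.30) and SSA2 (-1.46 ± 0.26), and 1 higher (1 higher and 10 lower adjusted over the list alone), and of 72 ribosome biogenesis genes 18 were lower, such as SIK1 (-1.06 ± 0.11; 17 adjusted over the list alone). The chaperone and ribosome biogenesis medians were -0.71 and -0.51 (camera adjusted p = 0.0011 and 2.3e-07). With an estimated correlation adjusted p was 0.57 for each. Of 45 DNA replication genes 15 were higher, such as PRI2 (1.49 ± 0.24), and 2 lower (16 higher and 3 lower adjusted over the list alone). The DNA replication median was 0.36 (camera adjusted p = 0.011, and adjusted p = 0.57 with an estimated correlation). The falls in chaperones became 4 (NaCl 2). The falls in ribosome biogenesis became 29 (YPD 1 or YPD 2), 11 (NaCl 1), 6 (NaCl 2) and 9 (sorbitol 1). The rises in the DNA replication list became 6 (NaCl 1) and 9 (sorbitol 1).

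Cytosolic ribosomal proteins were lower in NaCl than in sorbitol in 35 of 66 (52 adjusted over the list alone), a direction that turned under quantile normalization (median 0.09, 8 higher and 2 lower, adjusted p = 0.037). The ribosomal protein median was -0.48 (camera adjusted p = 8.4e-13, and adjusted p = 0.57 with an estimated correlation). Oxidative phosphorylation genes were lower in 27 of 51 and higher in 3 (3 higher and 30 lower adjusted over the list alone), and quantile normalization ended the call (median -0.11, adjusted p = 0.31). The oxidative phosphorylation median was -0.41 (camera adjusted p = 1.3e-07, and adjusted p = 0.57 with an estimated correlation). RPS42 (-2.16 ± 0.13), RPL9B (-1.49 ± 0.15) and COX13 (-0.88 ± 0.13) were lower, and IDP1 (3.71 ± 0.14) was higher. Mitochondrial ribosomal proteins had MRPL33 (-0.71 ± 0.15) and MRP17 (-1.11 ± 0.24) lower (2 adjusted over the list alone). The mitochondrial ribosomal median was -0.32 (camera adjusted p = 0.018, and adjusted p = 0.57 with an estimated correlation). Proteasome genes gained a list call under quantile normalization (median 0.23, adjusted p = 0.024). The falls in ribosomal proteins became 21 (YPD 1), 20 (YPD 2), 2 (NaCl 1), 12 (NaCl 2), 4 (sorbitol 1) and 15 (sorbitol 2). The falls in oxidative phosphorylation became 14 (NaCl 1), 13 (NaCl 2), 11 (sorbitol 1) and 12 (sorbitol 2). The falls in mitochondrial ribosomal proteins became 5 (YPD 1), 4 (YPD 2) and 1 (NaCl 1, NaCl 2 or sorbitol 2). Mitochondrial ribosomal proteins (adjusted p = 0.13 without sorbitol 2) lost the camera call. MRPL33 (NaCl 2 or sorbitol 1, up to 0.068) and MRP17 (NaCl 1 or sorbitol 2, up to 0.060) lost the call.

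In all, 1751 of 5765 genes differed, 967 higher and 784 lower in NaCl than in sorbitol (2445 at an unadjusted p under 0.05), 719 of them by at least 1 log2 unit. Camera called 9 lists, fry 11, and camera with an estimated correlation 0 (3 at an unadjusted p under 0.05). The count fell to 961 without NaCl 1, 1039 without NaCl 2 and 1142 without sorbitol 1.

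KCl against sorbitol showed higher AHP1 in KCl (76.5 ± 6.37 FPKM against 9.08 ± 0.529, n = 2 per medium; log2 change 2.94 ± 0.16, adjusted p = 9.8e-05), with the galactose-use genes GAL10 (2.03 ± 0.32) and GAL1 (1.88 ± 0.28) and the glyoxylate cycle genes ICL1 (1.94 ± 0.31) and MLS1 (1.87 ± 0.28). DIT1 (-3.03 ± 0.25), ERG3 (log2 change -2.04 ± 0.17, adjusted p = 6.7e-04), the inositol synthesis gene INO1 (-1.67 ± 0.21), CTR1 (-1.67 ± 0.17) and UPC2 (-1.50 ± 0.14) were lower. RHR2 (log2 change -1.3 ± 0.19, adjusted p = 0.010), GPD1 (-0.71 ± 0.14) and XYL2 (-0.91 ± 0.13) were lower and ARD (0.99 ± 0.19) higher (1 higher and 3 lower adjusted over the list alone; median 0.07, mean -0.21; camera adjusted p = 0.44). PHO89 (2.61 ± 0.38) and CNH1 (0.89 ± 0.16) were higher (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.55). HAK1 (-0.87, adjusted p = 0.11) was not called, but was without YPD 1 or YPD 2. TPS1 (-0.74 ± 0.13) and TPS2 (-0.83 ± 0.13) were lower (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.75). HOG pathway genes gave 0 of 19 calls by limma (2 at an unadjusted p under 0.05, 0 without the trend). GAL10, GAL1, XYL2 and TPS2 (KCl 2 or sorbitol 2, up to 0.088) and ICL1 (KCl 2 or sorbitol 1, up to 0.063) lost the call. MLS1, CNH1 and TPS1 (KCl 2, sorbitol 1 or sorbitol 2, up to 0.11) and GPD1 (KCl 1, KCl 2 or sorbitol 2, up to 0.15) lost the call. ARD (KCl 1, sorbitol 1 or sorbitol 2, up to 0.12) and PHO89 (sorbitol 2, up to 0.061) lost the call.

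Sterol genes were lower in KCl than in sorbitol in 9 of 26 (18 adjusted over the list alone), glycolytic genes in 7 of 17 (13 adjusted over the list alone), and DNA replication genes were higher in 5 of 45 (14 adjusted over the list alone). The sterol list median was -0.49 (camera adjusted p = 2.1e-14, and adjusted p = 0.17 with an estimated correlation). The glycolysis and DNA replication medians were -0.61 and 0.37 (camera adjusted p = 1.2e-08 and 2.0e-07). With an estimated correlation adjusted p was 0.41 for each. The other list calls had 0 or 1 member called. Of 18 heat shock genes only HSP78 was lower (-1.11 ± 0.22; 4 adjusted over the list alone), and of 72 ribosome biogenesis genes only SIK1 (-0.57 ± 0.11; 0 adjusted over the list alone). The chaperone list median was -0.42 (camera adjusted p = 2.9e-04, and adjusted p = 0.67 with an estimated correlation). The ribosome biogenesis median was -0.21 (camera adjusted p = 2.9e-04, and adjusted p = 0.78 with an estimated correlation). Translation factors, mitochondrial ribosomal proteins and the proteasome were called as lists with 0 members called by limma (8, 2 and 0 at an unadjusted p under 0.05, 0 without the trend). Their medians were -0.27, -0.30 and -0.12 (camera adjusted p = 1.7e-06, 0.0033 and 0.020). With an estimated correlation adjusted p was 0.67 for each. Cytosolic ribosomal proteins and oxidative phosphorylation lost their calls under quantile normalization, with medians of 0.03 and 0.03 (adjusted p = 0.55 and 0.097), as did the proteasome (-0.08, adjusted p = 0.36). The ribosomal protein median was -0.27 (camera adjusted p = 6.3e-11, and adjusted p = 0.67 with an estimated correlation). The oxidative phosphorylation median was -0.19 (camera adjusted p = 6.8e-04, and adjusted p = 0.72 with an estimated correlation). The falls in sterol synthesis became 5 (KCl 2, sorbitol 1 or sorbitol 2). The falls in glycolysis became 3 (NaCl 1 or NaCl 2), 0 (KCl 2 or sorbitol 2) and 2 (sorbitol 1). The rises in the DNA replication list became 3 (YPD 1, YPD 2 or KCl 1), 2 (NaCl 1 or NaCl 2) and 0 (KCl 2, sorbitol 1 or sorbitol 2). Ribosome biogenesis (adjusted p = 0.21 without KCl 2 and 0.47 without sorbitol 1) lost the camera call. Mitochondrial ribosomal proteins (adjusted p = 0.15 without sorbitol 2) lost the camera call. Proteasome (adjusted p = 0.16 without KCl 1 and 0.18 without sorbitol 2) lost the camera call. Oxidative phosphorylation and TCA cycle (adjusted p = 0.35 without KCl 2) lost the camera call. HSP78 (KCl 1, KCl 2 or sorbitol 2, up to 0.14) and SIK1 (any NaCl, KCl or sorbitol library, up to 0.14) lost the call.

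In all, 356 of 5765 genes differed between KCl and sorbitol, 210 higher and 146 lower in KCl (1215 at an unadjusted p under 0.05), 154 of them by at least 1 log2 unit. Camera called 10 lists, fry 4, and camera with an estimated correlation 0 (1 at an unadjusted p under 0.05). The count fell to 227 without NaCl 1, 228 without NaCl 2, 162 without KCl 1, 69 without KCl 2, 129 without sorbitol 1 and 60 without sorbitol 2.

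Genes that set 1 solute apart were those called the same way in both comparisons of that solute with the others. For sodium there were 348 higher and 211 lower, with 37 amino acid synthesis genes higher and 4 lower, 13 glycolytic and 8 sterol genes lower, and 4 cell wall genes higher. For potassium there were 7 higher and 7 lower. Those with a symbol were PHO89 (1.40 above NaCl and 2.61 above sorbitol), the glycine cleavage genes GCV1 (1.42 and 0.61) and GCV2 (1.45 and 0.71), FRE10 (0.74 and 0.70) and PMM1 (0.59 and 0.72), all higher, and MMD1 (-0.44 and -0.47) and KEL1 (-0.63 and -0.65), lower, and they were chosen for naming after their values were seen. Both salts differed from sorbitol in 195 genes that were higher and 126 that were lower, the lower ones including 9 sterol, 7 glycolytic and 3 glycerol or polyol genes and the higher ones 5 DNA replication genes. The 559 sodium genes became 211 without NaCl 1, 275 without NaCl 2 and 245 without KCl 1. The 14 potassium genes became 3 without NaCl 1, 4 without NaCl 2, 4 without KCl 1, 8 without KCl 2, 7 without sorbitol 1 and 1 without sorbitol 2, and the 321 genes of both salts 190 without NaCl 1, 185 without NaCl 2, 153 without KCl 1, 62 without KCl 2, 119 without sorbitol 1 and 60 without sorbitol 2.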

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

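Of the tests in this part, those on the YPD libraries, on gene length, on other abundant genes, on equal total FPKM and on genes below without each library were chosen only after the result was seen.

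Some genes moved in opposite directions in 2 media against YPD, with the difference between the 2 media also called. They were 8 between NaCl and KCl (5 with a symbol), 20 between NaCl and sorbitol (7) and 5 between KCl and sorbitol (2). Each difference sums 2 called changes at an equal standard error, so its test removed no gene and adds no support for opposite directions. NaCl minus KCl gave log2 differences of 3.62 for HAK1 (1.95 in NaCl and -1.67 in KCl against YPD), 2.12 for AAT1 (1.40 and -0.72), -1.40 for ADE6 (-0.70 and 0.70), -1.07 for SHM2 (-0.48 and 0.59) and -2.02 for RPS42 (-1.10 and 0.92). NaCl minus sorbitol gave -3.05 for ERG3 (-2.20 and 0.85), -2.78 for ITR1 (-1.76 and 1.02), -2.76 for DIT1 (-1.04 and 1.72), -2.37 for ERG1 (-1.69 and 0.67), -2.31 for FTR2 (-1.07 and 1.23), -2.16 for RPS42 (-1.10 and 1.06) and -1.06 for SIK1 (-0.45 and 0.61). KCl minus sorbitol gave -3.03 for DIT1 (-1.30 and 1.72) and -2.04 for ERG3 (-1.19 and 0.85). The largest adjusted p of these differences was 0.0011 (SHM2), and each was called without each of the 8 libraries and under the 3 scalings.

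The opposite directions rested on weaker calls against YPD, except for HAK1 and, between the salts, RPS42, whose calls held without each library. All 7 sorbitol calls were lost without YPD 1 (up to 0.16) or sorbitol 1 (up to 0.15), that of FTR2 also without YPD 2 (0.055), that of DIT1 without sorbitol 2 (0.052), and those of ITR1, SIK1, ERG1 and ERG3 without YPD 2, sorbitol 2 or either NaCl library (up to 0.098). Quantile normalization ended those of SIK1, ERG1 and ERG3 (0.10, 0.074 and 0.069). The NaCl calls of SHM2 and SIK1 were lost without any YPD or NaCl library (up to 0.11), that of ADE6 without YPD 1 or either NaCl library (up to 0.060) and that of DIT1 without YPD 2 or either NaCl library (up to 0.096). The KCl calls of AAT1, ADE6 and SHM2 were lost without either YPD library or KCl 1 (up to 0.13) and that of DIT1 without YPD 2 or KCl 2 (up to 0.074).

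Ribosome biogenesis was called higher as a list in all 3 media (30, 33 and 41 of 72 members rose in NaCl, KCl and sorbitol), while their list median in YPD 1 lay 0.50 log2 units below that in YPD 2. The lower sorbitol library lay 0.684 above YPD 2, more than the YPD libraries differed. That argues against a low YPD 1 as the whole cause there, though 2 libraries do not bound how far controls vary. In NaCl (0.184) and KCl (0.488) the distance was no larger than the difference between the YPD libraries. There a low YPD 1 and a response to the solute cannot be told apart with 2 controls. With the trend on gene length removed the smallest list median was 0.426 and the list was called in all 3 media (adjusted p = 0.73, 0.52 and 0.48 in NaCl, KCl and sorbitol with an estimated correlation), which argues against gene length. A response to the solutes stays open as an untested explanation.

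Heat shock was called lower as a list in both salts (13 and 8 of 18 members fell in NaCl and KCl), while their median in YPD 2 lay 0.532 above that in YPD 1. The higher NaCl library lay 0.675 below YPD 1, which argues against a high YPD 2 as the whole cause in NaCl. In KCl the distance was 0.462, so a high YPD 2 and a response to KCl cannot be told apart with 2 controls. With the trend on gene length removed the median nearest 0 was -0.857 and both calls held (adjusted p = 0.58 and 0.52 in NaCl and KCl with an estimated correlation), which argues against gene length. A response to the salts stays open as an untested explanation.

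Glycolytic genes, among the most abundant in YPD, fell in NaCl with a median of -1.23. The other 211 genes with at least 1000 FPKM in YPD had a median of -0.171 (interquartile range -0.473 to -0.0612), which argues against a loss of signal from all abundant genes. With every library scaled to the same total FPKM, which moved the median of all genes by 0.160, the list's median was -1.06 and 13 of 17 members were lower. That scaling moves all genes by nearly the same amount, so it could not have brought the list's median near 0. It shows only that the unequal totals are too small to account for a fall of this size. A response to NaCl is a hypothesis found and tested on the same data.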

How the results depend on the processing

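The counts of genes specific to a solute under each setting, list members without each library and the lists under quantile normalization were chosen only after the result was seen. Over the alternatives, 740 results of named genes gave 13262 values: 12277 kept direction and side of the threshold, 810 lost a call, 172 gained one and 3 reversed. Those 3 reversed under quantile normalization, between NaCl and sorbitol: PMA1 (-0.04 to 0.46, adjusted p = 0.037), RPP0 (-0.54 to 0.024) and TEF2 (-0.62 to 0). The 54 list calls gave 594 values under median-of-ratios and TMM scaling, the replicate block and removals, of which 573 kept the call and 21, all without a library, lost it. With an estimated correlation camera called 0 lists in each comparison (smallest adjusted p 0.222 for NaCl, 0.181 for KCl and 0.270 for sorbitol against YPD, 0.295 for NaCl and KCl, 0.213 for NaCl and sorbitol, 0.166 for KCl and sorbitol). Median-of-ratios and TMM factors were 0.982 to 1.016, so these 2 scalings hardly tested the calls. A pseudocount of 5 FPKM left 91 genes at 1 log2 unit or more between KCl and sorbitol. Without the trend limma called 112 genes in sorbitol (80 at 1 log2 unit or more) and 61 in all 3 media. With the replicate number as a block it called 516 in sorbitol, 536 between KCl and sorbitol, 219 in all 3 media and 37 specific to potassium. The block gave a call to 64 results of named genes, among them PHO89 and VCX1 in NaCl, RHR2 in sorbitol, GPD2 between the salts and HAK1 between KCl and sorbitol. Replicate differences correlated between media at -0.13 to 0.45, which does not settle whether the numbers pair libraries. With only the 4 libraries compared, 20 were called in sorbitol (20 at 1 log2 unit or more) and 90 between KCl and sorbitol (74), from a fit with fewer samples. For the other changes in this paragraph the cause was not tested. The remaining counts stayed within 1.5 times their value under these settings, no filter, a filter of 10 FPKM, a pseudocount of 0.1 and the scalings. Leaving out 1 library gave ranges of 701 to 1552 genes in NaCl, 114 to 610 in KCl and 4 to 245 in sorbitol against YPD, 223 to 563 between the salts, 961 to 1752 between NaCl and sorbitol and 60 to 264 between KCl and sorbitol. At 1 log2 unit or more the ranges were 509 to 726, 104 to 318, 4 to 168, 188 to 346, 634 to 743 and 58 to 130, and for lists 8 to 12, 7 to 11, 7 to 11, 6 to 7, 8 to 10 and 8 to 10. For all 3 media it was 4 to 114 genes, for sodium 211 to 480, for potassium 1 to 11 and for both salts 60 to 238. The correlation of changes ranged from 0.588 to 0.742 for NaCl and KCl, 0.255 to 0.439 for NaCl and sorbitol and 0.488 to 0.705 for KCl and sorbitol. With 1 library left, a medium was assumed to vary like the others. Named genes called in all 8 removals were 66 of 90, 31 of 64 and 1 of 38 in NaCl, KCl and sorbitol, 30 of 57 between the salts, 62 of 84 between NaCl and sorbitol and 12 of 44 between KCl and sorbitol. A DESeq2 test needs counts and was not run. Depth limits genes near 1 FPKM, where 1 fragment stood for 0.0299 to 0.0649 FPKM in a gene with 1 kb left after the length offset.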

Other observations

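All of these tests, on 8 further gene lists, were chosen only after the result was seen. Of 24 genes of nitrogen source use 14 rose and 4 fell in NaCl (9 rose without YPD 1 or NaCl 2; median 1.41, camera adjusted p = 0.0020, and adjusted p = 0.41 with an estimated correlation). Of 20 genes of beta-oxidation and the glyoxylate cycle 10 rose in NaCl (6 without NaCl 1; median 0.55, camera adjusted p = 0.0020, and adjusted p = 0.41 with an estimated correlation). Of 14 purine synthesis genes 12 were lower in NaCl than in KCl (6 without NaCl 1, 7 without NaCl 2 and 5 without KCl 1; median -0.73, camera adjusted p = 6.3e-11, and adjusted p = 0.27 with an estimated correlation) and 12 lower than in sorbitol (6 without NaCl 2 or sorbitol 1; median -0.76, camera adjusted p = 3.4e-06, and adjusted p = 0.36 with an estimated correlation). Against YPD 8 fell in NaCl (1 without YPD 1 or NaCl 1 and 3 without YPD 2 or NaCl 2) and 4 rose in KCl (0 by limma without YPD 1, YPD 2 or KCl 1), and the list was called higher in sorbitol (median 0.25, or 0.14 under quantile normalization; camera adjusted p = 0.0026, or 0.043, and adjusted p = 0.42 with an estimated correlation), where limma called 0 members (4 at an unadjusted p under 0.05, 0 without the trend). In NaCl the lists of sulfate assimilation (adjusted p = 0.098; 0.24 in KCl and 0.16 in sorbitol, or 0.045 without sorbitol 1), fatty acid synthesis (0.75), vacuolar ATPase (0.78) and mitochondrial protein import (0.82) were not called, nor was metal uptake (0.062; 0.030 without YPD 2, 0.028 without NaCl 1 and 0.044 without NaCl 2). Among other calls, camera called nitrogen source use higher in KCl (0.0063, or 0.17 without KCl 2; 0.69 with an estimated correlation), metal uptake lower in NaCl than in KCl (0.010; 0.27) and mitochondrial protein import higher in sorbitol (0.0030, or 0.21 without YPD 1 and 0.077 without sorbitol 2; 0.42).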
